A study of Mus musculus with 12 samples.

How the data were processed

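RNA was measured by sequencing in 12 libraries of PD1+ CD8 T cells from the spleens of 3 mice on day 16 of infection. Per the labels' protocols, the mice were Prdm1-EYFP animals on a B6 background, the splenocytes were sorted by flow cytometry, RNA was taken up in Trizol and cleaned with a Zymo Direct-zol kit, and libraries were made with the NEBNext Ultra II RNA kit. The series description adds that splenocytes were enriched for CD8 T cells with FlowComp beads before the sort. The sort gates come from the sample titles, and each title ends in a number (45, 49 or 54) that marks the mouse, so the 4 libraries with one number come from one animal. The numbers in the table's column names were matched to those in the labels' descriptions, and no column was left unmatched.

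The submitters' processing notes name bcl2fastq, STAR 2.0.4b, Subread, featureCounts 1.4.5, edgeR, limma and DESeq2, without the role or order of each. The genome build, the annotation and the strandedness of the libraries are not given in the sources used here. Reads of close paralogs, such as members of the Klra, Bcl2a1, granzyme, histone and ribosomal protein families, may have been assigned to one another or dropped, and this cannot be seen in a table per gene. The authors deposited one table of 14512 lines with Ensembl mouse gene IDs. Its values per library are log2 CPM as the authors deposited them, and by their form each is the log2 of a whole number of reads plus 0.5, over a library size that is not the sum of the reads. Per the file headers, the table also holds the authors' log2 fold changes with their confidence limits, a p-value and an adjusted p-value for each of the 6 comparisons, and a mean log2 level over the 12 libraries. The headers do not name the program that gave them.

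Of the 14512 lines, 51 repeated a gene ID with identical values and were dropped, which left 14461 genes. Symbols stored as dates (21) were replaced by the GENCODE M21 symbol of the same Ensembl ID. GENCODE M21, on GRCm38, holds 14450 of the IDs, and 12833 genes of the table are protein-coding. It was used for symbols, gene types, coordinates, exonic length and GC content. Reads were recovered from the log2 values with the value of 0 reads in each library, and 100.0% of the values came back within 0.02 of a whole number. Recovered reads ran from 5646977 to 10432475 per library. The deposited library sizes were 0.92 to 1.12 of these totals, with means of 1.071 in the YFP-negative population, 1.021 in Tim3−CX3CR1+, 0.968 in Tim3+CX3CR1− and 0.950 in Tim3+CX3CR1+. At this depth, and with 3 libraries per population, the median standard error of a log2 change was 0.121 over the genes tested. Depth, unlike the number of mice, sets the counting error alone.

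Before the data were examined, the 6 comparisons, the test for counts and for CPM, the gene lists, the rule for the genes named and a first set of alternatives were written down. That plan assumed a table of counts or of CPM, and the deposited values are log2 CPM, so they were turned back into CPM and the test planned for CPM was used. Genes with at least 1 CPM in at least 3 libraries were kept (14407, with 54 removed). The test was limma with a trend on log2(CPM + 1), all 4 populations in 1 fit without a term for the mouse, and Benjamini-Hochberg adjustment over the genes of a comparison at 0.05. The pseudocount of 1 draws the changes of low genes towards 0. A gene counted as highest in a population if it was called higher there than in each of the other 3.

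Gene lists (26) were tested with camera on the same values and fit, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 25 lists that had at least 5 measured genes. The program lists are progenitor-like exhausted, inhibitory receptors, exhaustion and effector transcription factors, cytotoxic granule and killing, CX3CR1 KLRG1 effector, NK receptors, G2 and M phase, S phase, cytokines and chemokines, trafficking receptors, interferon-stimulated, immediate early and TCR-induced, quiescence, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, tissue residency and apoptosis regulators. The other 7 hold markers of B cells, plasma cells, macrophages and monocytes, neutrophils, dendritic cells, erythroid cells and platelets, and CD4 T cells. For these the CPM of the markers were also summed per library and compared by exact permutation, where 3 libraries against 3 can give no p below 0.1.

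The genes named are the 16 panel genes in every comparison, called or not, and the 5 highest and 5 lowest changes per comparison among called genes that moved the same way in all 3 mice. These had at least 10 CPM in the higher population and were no predicted genes, pseudogenes or receptor segments. Up to 2 of the highest and 2 of the lowest called members of each list and 8 genes per population for the counts of highest genes, by the smallest margin over the other 3, complete the rule. Some genes that the rule names are not reported here.

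The alternatives written beforehand and run were no filter, pseudocounts of 0.25 and 5, limma-voom on the recovered reads, the mouse as a block, the 6 libraries of a comparison alone, and each library left out in turn. For the lists they were a correlation between genes estimated per list, the self-contained test fry and the mouse as a block. Chosen after seeing the data were the deposited log2 values as they are, scaling by total reads, median-of-ratios scaling, array weights, log2 Gm42418 (a locus that overlaps ribosomal RNA) as a covariate, the log2 sum of major satellite loci as a covariate, and leaving out the 4 libraries of a mouse. The Gm42418 covariate partly stands for the Tim3+CX3CR1− population, where its highest values lie, so that fit also removes some differences of that population. The mouse block rests on the labels, since libraries with one number come from one animal. As a check, deviations from the population means of the same mouse correlated between populations at r = -0.49 to 0.49, with 6 of 18 pairs above 0.1.

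The gene test was tested on simulated reads for each comparison, with 200 genes changed by 1.5-, 2- or 4-fold. At 1.5-fold it recovered 44.8% for Tim3−CX3CR1+ over YFP-negative, 59.7% for Tim3+CX3CR1+ over YFP-negative, 47.8% for Tim3+CX3CR1− over YFP-negative, 50.7% for Tim3+CX3CR1+ over Tim3−CX3CR1+, 59.7% for Tim3+CX3CR1− over Tim3+CX3CR1+ and 53.7% for Tim3+CX3CR1− over Tim3−CX3CR1+ (67 genes each). At 2-fold (67 genes) the shares were 70.1%, 62.7%, 71.6%, 73.1%, 71.6% and 65.7% in the same order, and at 4-fold (66 genes) 77.3%, 77.3%, 92.4%, 75.8%, 80.3% and 89.4%. Of the calls made, 2.92% to 7.33% were genes left unchanged. The simulated reads had few changed genes, independent noise per gene and scaling by total reads. This share therefore need not hold for the comparisons of the data. In the list test 3% of 200 unchanged random lists of 20 genes had p under 0.05, and a list shifted by 0.5 log2 was found. Genes were drawn independently there, so this cannot test the preset correlation for lists whose members vary together. The estimated correlation was 0.701 for interferon-stimulated genes and 0.543 for G2 and M phase genes. Values were computed with R 4.3.3 and limma 3.58.1, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not used here.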

Results

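Gene expression was measured by bulk RNA sequencing in CD8 T cells from the spleens of 3 mice that carried a Prdm1-EYFP reporter, in which yellow fluorescent protein (YFP) reads out Prdm1, the gene of the transcription factor Blimp1. The mice had been infected with clone 13 of lymphocytic choriomeningitis virus, a strain that persists and leaves CD8 T cells in a state called exhaustion, and the spleens were taken on day 16. PD1+ cells of each mouse were sorted by flow cytometry into 4 populations by Tim3 (the protein of Havcr2), CX3CR1 and YFP. These were Tim3−CX3CR1−YFP− cells, called the YFP-negative population here, and 3 YFP+ populations called Tim3−CX3CR1+, Tim3+CX3CR1+ and Tim3+CX3CR1−. Each population had 3 libraries, from mice 45, 49 and 54, which made 12 libraries in all, and each mouse gave all 4 populations. Recovered reads per library were 7740033, 8391248 and 8741926 in the YFP-negative population (mice 45, 49 and 54) and 8093023, 5646977 and 7691479 in Tim3−CX3CR1+. They were 8944619, 10432475 and 8424636 in Tim3+CX3CR1+ and 7910361, 9695509 and 8195175 in Tim3+CX3CR1−. Levels are given as mean CPM (counts scaled to library size) ± SD over the 3 libraries of a population (n = 3), and changes as differences of mean log2(CPM + 1), which understate the change of genes near 1 CPM.

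Replicate libraries of a population correlated at r = 0.972 to 0.984 across genes, which are not independent replicates, and no replicate pair differed as little as sampling noise allows (chi-square per degree of freedom 2.94 to 23.65). The first principal component held 48.3% of the variance. It ran from the YFP-negative libraries (49.8 to 55.7) through Tim3−CX3CR1+ (1 to 12.8) to the Tim3+ libraries (-33.2 to -25.7). The second component held 25.6% and had the Tim3−CX3CR1+ libraries at its low end. The 10 most abundant genes of a library took 3.8% to 6.1% of its reads.

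Transcripts of Prdm1, Havcr2 and Cx3cr1 were higher in populations gated positive than in those gated negative, but also differed between populations of the same gate. Prdm1 (chromosome 10, 44437177 to 44528501 on GRCm38) stood at 18.1 ± 5.78 CPM in the YFP-negative population and at 219 ± 5.96, 343 ± 10.9 and 336 ± 7.37 CPM in Tim3−CX3CR1+, Tim3+CX3CR1+ and Tim3+CX3CR1−. Havcr2 (chromosome 11, 46454935 to 46481255) stood at 3.44 ± 0.893, 70.4 ± 10.8, 329 ± 12.4 and 298 ± 17.1 CPM in the same order. Cx3cr1 (chromosome 9, 119901616 to 120069879) stood at 9.08 ± 1.17, 703 ± 96.1, 482 ± 62.9 and 28.3 ± 3.95 CPM. Pdcd1, which encodes PD1 (chromosome 1, 94038305 to 94052553), stood at 248 ± 18.4, 261 ± 37.9, 571 ± 22.6 and 472 ± 11.9 CPM. Between populations whose gates differ in YFP, Tim3 or CX3CR1, the transcript of that marker checks the sort and is no finding, and these genes are included in the panel counts below. The gene lists hold them too. Cx3cr1 is in the CX3CR1 KLRG1 effector and trafficking lists, Havcr2 among inhibitory receptors, and Prdm1 in the transcription factor and tissue residency lists. Member counts and camera tests of these lists include them. Within the Tim3− gate Havcr2 stood at 3.44 CPM in YFP-negative and 70.4 CPM in Tim3−CX3CR1+. Within the CX3CR1− gate Cx3cr1 stood at 9.08 CPM in YFP-negative and 28.3 CPM in Tim3+CX3CR1−. All 4 populations shared the PD1+ gate, though Pdcd1 was higher in the Tim3+ populations. Tcf7, the gene of the progenitor factor TCF1, fell from 1340 ± 158 CPM in the YFP-negative population through 104 ± 12.7 in Tim3−CX3CR1+ to 13.1 ± 3.56 in Tim3+CX3CR1+ and 12.4 ± 2.43 in Tim3+CX3CR1−. Gzmb, which encodes granzyme B, stood at 52.9 ± 13.4, 1270 ± 372, 2610 ± 102 and 2230 ± 86.7 CPM, and Mki67, a proliferation marker, at 335 ± 54.5, 488 ± 124, 1290 ± 143 and 1500 ± 64.7 CPM. Cd101 was near 20 CPM in every population (20.5 ± 0.949, 19.5 ± 2.31, 20.3 ± 2.55 and 23.0 ± 3.05) and passed the test in none of the 6 comparisons.

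**Figure D1:**
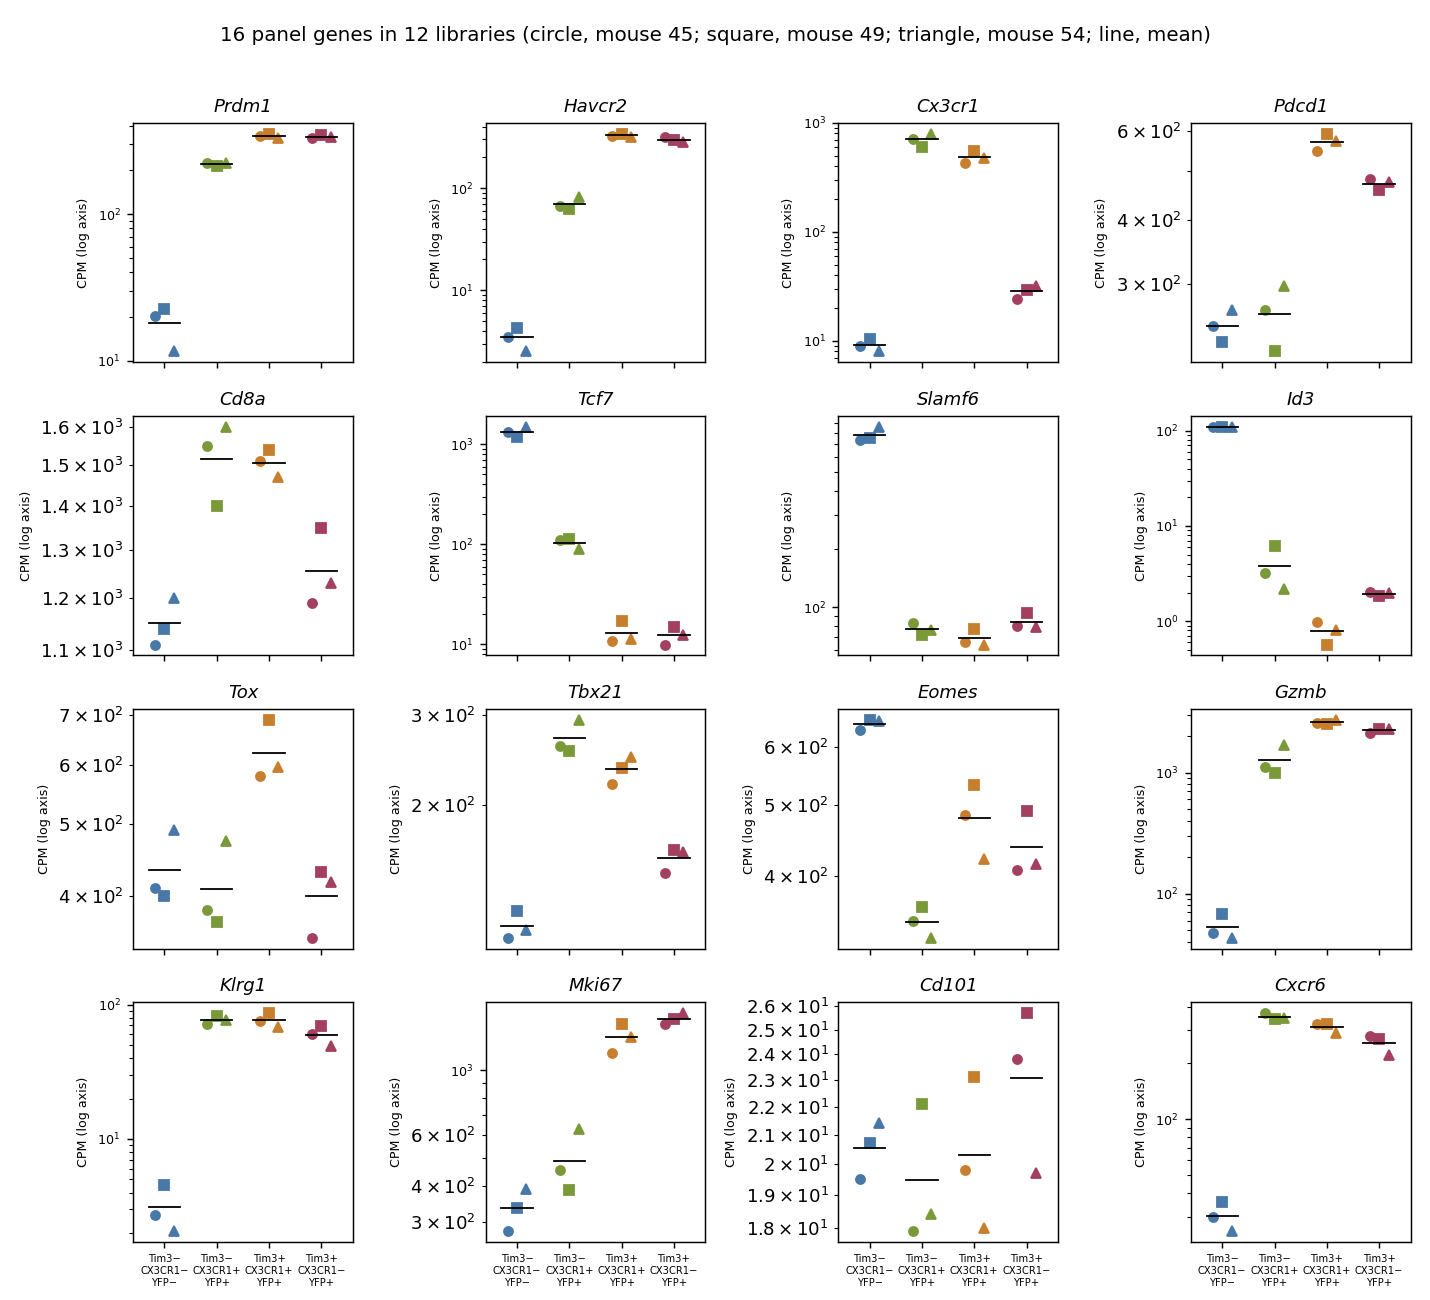
Levels of 16 panel genes in CPM (log axis) in the 12 libraries, with the 4 populations along the horizontal axis, a symbol for each mouse and a line at the mean of 3 libraries. Tcf7 means run from 1340 CPM in the YFP-negative population to 12.4 CPM in Tim3+CX3CR1−, and Cx3cr1 means from 9.08 to 703 CPM.

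Among 14407 genes tested, limma called 5895 genes at an adjusted p under 0.05 for Tim3−CX3CR1+ over YFP-negative, 6925 for Tim3+CX3CR1+ over YFP-negative and 7609 for Tim3+CX3CR1− over YFP-negative. Among the YFP+ populations it called 5199 for Tim3+CX3CR1+ over Tim3−CX3CR1+, 7398 for Tim3+CX3CR1− over Tim3−CX3CR1+ and 3407 for Tim3+CX3CR1− over Tim3+CX3CR1+. In fits without the 4 libraries of mouse 45 or of mouse 49, chosen after seeing the data, the 5199 became 3104 and 3434 and the 3407 became 1656 and 2243. Most differences were small: 431 of the genes higher in Tim3−CX3CR1+ than in the YFP-negative population and 637 of the lower ones differed by 2-fold or more, and for Tim3+CX3CR1− over Tim3+CX3CR1+ these were 83 and 53. Over all genes tested, called or not, 55.8% to 69.9% moved the same way in all 3 mice, against 25% by chance. The authors' deposited table lists 6309, 7633, 8047, 6255, 4616 and 8174 genes at its adjusted p under 0.05 for Tim3−CX3CR1+, Tim3+CX3CR1+ and Tim3+CX3CR1− over YFP-negative, Tim3+CX3CR1+ over Tim3−CX3CR1+, Tim3+CX3CR1− over Tim3+CX3CR1+ and Tim3+CX3CR1− over Tim3−CX3CR1+. It holds 93.7% to 99.8% of the genes called here, none in the opposite direction. The split into higher and lower genes rested on the deposited scaling. With libraries scaled by their total reads, an alternative chosen after seeing the data, the share of higher genes went from 46.8% to 36.2% for Tim3−CX3CR1+ over YFP-negative and from 54.4% to 36.4% for Tim3+CX3CR1+ over YFP-negative. It went from 52.1% to 39.6% for Tim3+CX3CR1− over YFP-negative and from 59.1% to 41.6% for Tim3+CX3CR1+ over Tim3−CX3CR1+. For Tim3+CX3CR1− over Tim3−CX3CR1+ it went from 52.1% to 44.6%, and for Tim3+CX3CR1− over Tim3+CX3CR1+ the other way, from 47.1% to 52.5%. The median change of all genes went from -0.04 to -0.18, -0.02 to -0.13 and -0.01 to -0.11 for Tim3+CX3CR1+ over YFP-negative, Tim3+CX3CR1− over YFP-negative and Tim3+CX3CR1+ over Tim3−CX3CR1+, and from -0.07 to -0.14 for Tim3+CX3CR1− over Tim3−CX3CR1+. Changes below are relative to the deposited scaling, under which these medians lie near 0.

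**Figure D2:**
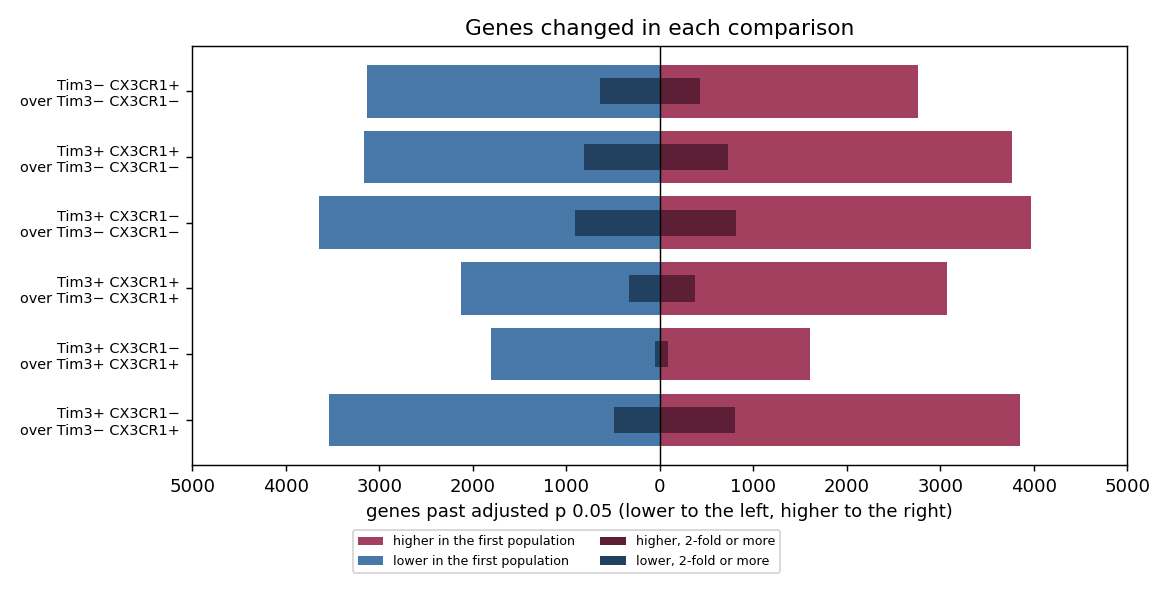
Genes past an adjusted p of 0.05 in each of the 6 comparisons, as bars from 0, lower in the first-named population to the left and higher to the right, with genes that differed by 2-fold or more in the dark bars. The comparisons with the YFP-negative population and Tim3+CX3CR1− over Tim3−CX3CR1+ hold 5895 to 7609 genes, and Tim3+CX3CR1− over Tim3+CX3CR1+ holds 3407.

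The first comparison sets the Tim3−CX3CR1+ population, the YFP+ cells without Tim3, against the YFP-negative population. Tim3−CX3CR1+ cells carried more transcripts of effector, cytotoxic and NK-receptor genes and fewer of progenitor genes by camera. The cytotoxic and NK receptor lists did not pass with an estimated correlation between genes. Besides Cx3cr1 (6.12 ± 0.12 SE), the highest changes were in Gzma, a granzyme (526 ± 132 against 13.6 ± 2.92 CPM, log2 change 5.16), and Itgam, the CD11b integrin (185 ± 25.2 against 4.62 ± 0.925, 5.05). Next came Cmklr1, the chemerin receptor (4.99), and S1pr5, a sphingosine-1-phosphate receptor (86.3 ± 7.58 against 1.86 ± 0.143, 4.93). The lowest were in Nsg2 (2.60 ± 0.247 against 256 ± 21.4 CPM, -6.16), the chemokine Xcl1 (2.10 ± 0.616 against 123 ± 14.7, -5.34) and the homing receptor Ccr7 (1.56 ± 0.365 against 81.8 ± 18.7). They were followed by the coactivator gene Pou2af1 (-4.77) and by Id3, an inhibitor of E proteins (3.84 ± 2.06 against 110 ± 0.650, -4.60). All 10 passed limma with adjusted p from 3.59e-15 to 1.80e-10. Of the 16 panel genes 9 rose, 4 fell and 3 did not pass. Prdm1 (3.58), Havcr2 (4.02), Gzmb (4.54), Klrg1 (4.29), Cxcr6 (3.52), Tbx21 (1.21), Mki67 (0.53) and Cd8a (0.41) rose with Cx3cr1, and Tcf7 (-3.67), Slamf6 (-3.33) and Eomes (-0.89) fell with Id3. Pdcd1 stood at 0.07, Tox at -0.09 and Cd101 at -0.08 (limma adjusted p = 0.557, 0.534 and 0.624).

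All 20 genes of the progenitor-like list fell in Tim3−CX3CR1+ (median -3.25, camera adjusted p = 8.20e-22, adjusted p = 0.0161 with an estimated correlation). All 18 of the CX3CR1 KLRG1 effector list rose (median 1.98, camera adjusted p = 8.72e-21, adjusted p = 0.0171 with an estimated correlation). All 12 NK receptors rose, among them Cd244 (3.79) and Klra3 (3.44), with camera adjusted p = 6.94e-09 and adjusted p = 0.0916 with an estimated correlation. Of 17 cytotoxic genes 12 rose and 2 fell, Cst7 (-0.70) and Lamp1 (-0.67), with camera adjusted p = 1.47e-05 and adjusted p = 0.117 with an estimated correlation. Trafficking receptors went both ways, 13 of 20 up and 5 down, with Ccr7, which guides cells into lymph nodes, among those that fell (camera adjusted p = 0.000770, adjusted p = 0.269 with an estimated correlation). In the immediate early and TCR-induced list 15 of 21 fell, such as Egr2 (4.28 ± 1.12 against 81.8 ± 19.4 CPM, -3.97) and Egr3 (-2.71), with Fosl2 and Ier2 higher (camera adjusted p = 1.06e-06, adjusted p = 0.307 with an estimated correlation). Interferon-stimulated genes fell in 14 of 25, with Ifi44 at -2.07 and Oasl2 at -1.98, and Ifit2 rose (camera adjusted p = 0.000999, adjusted p = 0.607 with an estimated correlation). Of 24 ribosomal protein genes 18 fell, Rps2 (-0.80) the most, with camera adjusted p = 1.24e-07 and adjusted p = 0.105 with an estimated correlation. G2 and M phase genes rose in 16 of 20 by a median of 0.43 (camera adjusted p = 1.06e-06, adjusted p = 0.332 with an estimated correlation), and S phase genes in 6 of 20 with 1 lower (camera adjusted p = 0.192).

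Camera passed none of the other program lists for Tim3−CX3CR1+ over YFP-negative, which are given as members higher and lower. Inhibitory receptors had 6 and 5 of 13 (Btla -2.49), exhaustion and effector transcription factors 7 and 7 of 20 (Zeb2 2.32, Nr4a3 -2.39), and cytokines and chemokines 6 and 6 of 13 (Ccl5 6060 ± 102 against 421 ± 108 CPM, Tnf -3.07). Quiescence genes had 6 and 7 of 20 (Klf2 1.24), glycolysis 3 and 7 of 16 (Tpi1 -0.89) and oxidative phosphorylation 7 and 4 of 23. Cholesterol synthesis had 3 and 2 of 19, tissue residency 5 and 3 of 14 (P2rx7 -4.37) and apoptosis regulators 6 and 2 of 17 (Pmaip1 0.98). Adjusted over the list alone, the counts differed only in G2 and M phase (18 higher), S phase (5 higher), trafficking (14 higher), transcription factors (8 lower), immediate early genes (16 lower), ribosomal proteins (19 lower) and macrophage markers (6 higher, against 4). Summed B cell markers were lower in Tim3−CX3CR1+ as well (3 of 5 fell, Ighm and Cd22 among them, camera adjusted p = 0.0164, adjusted p = 0.117 with an estimated correlation). Leaving out all 4 libraries of mouse 45, an alternative chosen after seeing the data, ended the call of Mki67 (0.44, limma adjusted p = 0.0819, range over its alternatives 4.64e-05 to 0.0819). Under total-read scaling the median of oxidative phosphorylation genes turned from 0.06 to -0.01 and that of cholesterol synthesis from 0.01 to -0.05.

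The Tim3+CX3CR1+ population, YFP+ cells with both surface markers, was compared with the YFP-negative population next. Tim3+CX3CR1+ cells had higher cytotoxic and cell cycle transcripts and lower progenitor transcripts by camera. Of these list calls, with an estimated correlation between genes, that of the progenitor-like list alone passed. The highest changes were in Havcr2 (6.23 ± 0.12 SE), Itgam (278 ± 27.5 against 4.62 ± 0.925 CPM, 5.64), Gzmb (5.62), Cx3cr1 (5.58) and Cmklr1 (109 ± 8.26 against 1.45 ± 0.199, 5.48). The lowest were in Nsg2 (0.840 ± 0.541 against 256 ± 21.4, -7.17), Tcf7 (-6.59) and the nuclear factor gene Aff3 (-6.09). After them came Id3 (0.786 ± 0.207 against 110 ± 0.650, -5.96) and P2rx7, an ATP-gated channel (1.06 ± 0.343 against 96.4 ± 0.556, -5.58). All 10 passed limma with adjusted p from 1.70e-15 to 7.35e-11. In the panel 11 genes rose and 4 fell. Prdm1 (4.22), Klrg1 (4.28), Cxcr6 (3.34), Mki67 (1.95), Pdcd1 (1.20), Tbx21 (1.01), Tox (0.52) and Cd8a (0.40) rose besides Havcr2, Gzmb and Cx3cr1. Slamf6 (-3.49) and Eomes (-0.43) fell besides Tcf7 and Id3, and Cd101 stood at -0.02 (limma adjusted p = 0.904).

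All 20 progenitor-like genes fell in Tim3+CX3CR1+ (median -3.48, camera adjusted p = 3.29e-21, adjusted p = 0.0177 with an estimated correlation). All 20 G2 and M phase genes rose, by a median of 1.97 (Ube2c 2.39, Ccna2 2.31), and so did all 20 S phase genes, by 1.28 (Rrm2 1.88). Camera gave these lists adjusted p = 1.55e-19 and 1.78e-16, and adjusted p = 0.0712 with an estimated correlation for each. CX3CR1 KLRG1 effector genes rose in 16 of 18 (camera adjusted p = 2.79e-11, adjusted p = 0.0712 with an estimated correlation). Cytotoxic genes rose in 12 of 17, with Gzma at 5.45 and with Gzmm (-1.36) among the 3 that fell (camera adjusted p = 2.78e-05, adjusted p = 0.102 with an estimated correlation). Inhibitory receptors rose in 9 of 13, such as Cd244 (74.7 ± 11.8 against 1.87 ± 0.703 CPM, 4.74), while Btla (-2.08) and Ctla4 (-0.47) fell (camera adjusted p = 0.000701, adjusted p = 0.161 with an estimated correlation). Of 20 exhaustion and effector transcription factors 13 rose, among them Id2 (1.53), and Ikzf2 (-0.83) fell with Eomes (camera adjusted p = 0.00116, adjusted p = 0.223 with an estimated correlation). NK receptors rose in 8 of 12 (camera adjusted p = 0.000701, adjusted p = 0.218 with an estimated correlation). Apoptosis regulators rose in 11 of 17, with the survival gene Bcl2 among the 3 lower at -0.60 (camera adjusted p = 0.00998, adjusted p = 0.0712 with an estimated correlation). Ribosomal protein genes fell in 21 of 24 (camera adjusted p = 3.22e-07, adjusted p = 0.0712 with an estimated correlation). Interferon-stimulated genes fell in 18 of 25 (camera adjusted p = 6.56e-07, adjusted p = 0.299 with an estimated correlation). Quiescence genes fell in 15 of 20, led by Ccr7 (-5.42) and Il7r (-5.36), with 4 higher (camera adjusted p = 2.78e-05, adjusted p = 0.223 with an estimated correlation).

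Metabolic lists were higher in Tim3+CX3CR1+ by small amounts. Glycolysis genes rose in 11 of 16 (Slc2a3 1.10), oxidative phosphorylation genes in 17 of 23 with 1 lower (Cox7a2 0.77) and cholesterol synthesis genes in 10 of 19 with Mvk lower. Camera gave adjusted p = 0.00428, 0.000202 and 0.0125, and adjusted p = 0.293, 0.237 and 0.418 with an estimated correlation. With libraries scaled by total reads these counts were 8 higher and 3 lower, 9 higher and 2 lower, and 7 higher and 2 lower. Camera passed none of cytokines and chemokines (7 higher and 5 lower of 13, Ccl3 4.30, Ccl4 4.09, Xcl1 -3.91), trafficking receptors (12 and 6 of 20, Cxcr5 -4.39), immediate early genes (5 and 8 of 21, Tnfrsf9 1.08, Egr2 -1.99) and tissue residency genes (6 and 3 of 14). Adjusted over the list alone, the counts differed in transcription factors (14 higher), NK receptors (9 higher), interferon-stimulated genes (19 lower), immediate early genes (6 higher), cholesterol synthesis (11 higher), B cell markers (4 lower, against 3) and dendritic cell markers (1 lower, against 0). B cell markers fell in 3 of 5 in Tim3+CX3CR1+ (camera adjusted p = 0.00265, adjusted p = 0.0712 with an estimated correlation), and Ighm was at 121 ± 9.86 against 317 ± 45.1 CPM.

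In the third comparison, Tim3+CX3CR1− cells, YFP+ with Tim3 but without CX3CR1, were set against the YFP-negative population. They had higher cell cycle and metabolic transcripts and lower progenitor, quiescence and interferon-stimulated transcripts by camera. With an estimated correlation between genes, the progenitor-like list alone passed among these. The highest changes were in Havcr2 (6.09 ± 0.12 SE), Gzmb (5.40), Gzma (511 ± 81.2 against 13.6 ± 2.92 CPM, 5.14). Next were Adgrg1, which encodes the adhesion receptor GPR56 (4.40), and Cd244, the receptor 2B4 (53.9 ± 2.21 against 1.87 ± 0.703, 4.29). The lowest were in Tcf7 (-6.65), Nsg2 (-6.33), Aff3 (-5.69), Id3 (-5.23) and Il7r, the interleukin 7 receptor (5.13 ± 0.581 against 210 ± 59.8, -5.08). All 10 passed limma with adjusted p from 4.92e-15 to 1.03e-11. Of the panel 9 rose and 4 fell. Prdm1 (4.19), Klrg1 (3.92), Cxcr6 (3.04), Mki67 (2.17), Cx3cr1 (1.53), Pdcd1 (0.93) and Tbx21 (0.44) rose with Havcr2 and Gzmb, and Slamf6 (-3.21) and Eomes (-0.56) fell with Tcf7 and Id3. Cd8a (0.13), Tox (-0.12) and Cd101 (0.15) had limma adjusted p = 0.155, 0.395 and 0.323. Tox passed under total-read scaling (-0.26, limma adjusted p = 0.0185) and Cd8a with log2 Gm42418 as a covariate (0.19, limma adjusted p = 0.0482, range over its alternatives 0.0482 to 0.870).

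All 20 progenitor-like genes fell (median -2.94, camera adjusted p = 2.75e-18, adjusted p = 0.0299 with an estimated correlation). All 20 G2 and M phase genes and all 20 S phase genes rose, with Ccna2 at 2.53 and Rrm2 at 2.51. For these lists camera gave adjusted p = 2.75e-18 and 6.92e-18, and adjusted p = 0.147 and 0.115 with an estimated correlation. Oxidative phosphorylation genes rose in 20 of 23 (Cox5a 1.06, Ndufb8 1.02), glycolysis genes in 14 of 16 (Slc16a3 1.37, Tpi1 1.25) and cholesterol synthesis genes in 16 of 19 (Cyp51 1.41, Sqle 1.28). Camera gave the metabolic lists adjusted p = 5.86e-09, 2.37e-06 and 1.24e-05, and adjusted p = 0.161, 0.164 and 0.196 with an estimated correlation. Interferon-stimulated genes fell in 22 of 25, such as Oasl2 (3.31 ± 1.06 against 36.6 ± 6.84 CPM, -3.14) and Ifit3 (-2.70), with camera adjusted p = 2.43e-10 and adjusted p = 0.229 with an estimated correlation. Quiescence genes fell in 18 of 20, and Klf6 (0.61) rose (camera adjusted p = 1.95e-09, adjusted p = 0.161 with an estimated correlation). Cytotoxic genes went up in 11 and down in 4 of 17, with Gzmm (-1.07) and Lamp1 (-0.93) lower (camera adjusted p = 0.00153, adjusted p = 0.196 with an estimated correlation). Inhibitory receptors went up in 9 and down in 2 of 13 (camera adjusted p = 0.00315, adjusted p = 0.196 with an estimated correlation). CX3CR1 KLRG1 effector genes rose in 12 of 18, including Itgam (3.69), while Klf3 (-1.25) and As3mt (-0.69) were among 4 that fell (camera adjusted p = 0.000382, adjusted p = 0.196 with an estimated correlation). Ribosomal protein genes fell in 10 of 24 (17 under total-read scaling), with camera adjusted p = 0.0271 and adjusted p = 0.374 with an estimated correlation.

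The lists that camera did not pass for Tim3+CX3CR1− over YFP-negative began with transcription factors (12 higher and 2 lower of 20, or 9 and 6 under total-read scaling) and NK receptors (7 and 3 of 12, Klrk1 -0.99). Cytokines and chemokines (7 and 4 of 13, Ccl3 4.10, Ccl4 3.92, Lta -2.60) did not pass either. The same held for trafficking receptors (10 and 7 of 20, Ccr2 2.05, Cxcr5 -3.53) and immediate early genes (5 and 8 of 21, Tnfrsf9 1.27, Jun -1.64). Tissue residency (8 and 3 of 14) and apoptosis regulators (9 and 4 of 17) complete the lists without a pass. Bcl2, an inhibitor of apoptosis, fell from 299 ± 37.5 to 93.1 ± 13.7 CPM (-1.67, limma adjusted p = 3.02e-08). The trafficking list had a median of 0.13 and a mean of -0.19, and its median was -0.01 under total-read scaling. Adjusted over the list alone, the counts differed in transcription factors (3 lower), trafficking (8 lower), interferon-stimulated genes (23 lower), cholesterol synthesis (17 higher and 1 lower), tissue residency (5 lower) and dendritic cell markers (0 lower, against 1). B cell markers fell in 4 of 5 in Tim3+CX3CR1− (camera adjusted p = 0.0129, adjusted p = 0.147 with an estimated correlation).

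Within the YFP+ CX3CR1+ cells, Tim3+CX3CR1+ was compared with Tim3−CX3CR1+, a contrast that sets cells with Tim3 against cells without it. By camera, the cytokine and chemokine, cell cycle, TCR-induced and inhibitory receptor lists were higher in the Tim3+ cells, and none of these lists passed with an estimated correlation between genes. The highest changes were in Glp1r, the GLP-1 receptor (11.2 ± 2.16 against 1.16 ± 0.0825 CPM, 2.48 ± 0.19 SE), and the serine protease gene Tmprss6 (13.6 ± 4.21 against 1.62 ± 0.414, 2.45). Next were the chemokine gene Ccl4 (296 ± 23.4 against 56.0 ± 4.94, 2.38), the protease inhibitor gene Serpine2 (2.33) and Ccl3 (451 ± 41.2 against 89.6 ± 15.5, 2.33). The lowest were in Tcf7 (-2.92), Tnfrsf25, a TNF receptor family member (3.03 ± 0.530 against 22.1 ± 3.79, -2.52), and Klrb1c, which encodes NK1.1 (-2.45). They were followed by Nt5e, the CD73 ectoenzyme (1.38 ± 0.261 against 11.3 ± 1.91, -2.37), and Il7r (-2.19). All 10 passed limma with adjusted p from 2.73e-10 to 1.49e-05. In the panel, Prdm1 (0.64), Havcr2 (2.22), Pdcd1 (1.13), Tox (0.61), Eomes (0.46), Gzmb (1.08) and Mki67 (1.43) rose, and Cx3cr1 (-0.54) and Id3 (-1.36) fell with Tcf7. Cd8a (-0.01), Slamf6 (-0.16), Klrg1 (-0.01), Cd101 (0.06) and Cxcr6 (-0.18) did not pass (limma adjusted p = 0.923, 0.161, 0.967, 0.732 and 0.201). Tbx21 stood at -0.20 (limma adjusted p = 0.0428, range over its alternatives 0.00168 to 0.191). Without the Tim3+CX3CR1+ library of mouse 45 or 49 or the Tim3−CX3CR1+ library of mouse 45 or 54, it was at -0.15, -0.21, -0.22 and -0.14, with limma adjusted p = 0.159, 0.0788, 0.0628 and 0.162. Slamf6 passed in 4 of its 21 alternatives and Cxcr6 in 1, with limma adjusted p down to 0.00313 and 0.0348.

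All 20 G2 and M phase genes rose in Tim3+CX3CR1+ over Tim3−CX3CR1+ by a median of 1.59 (Bub1 1.79, Cdk1 1.77) and all 20 S phase genes by 1.27 (Cdc45 1.68). The cell cycle lists had camera adjusted p = 3.15e-25 and 1.74e-23, and adjusted p = 0.105 with an estimated correlation for each. Inhibitory receptors rose in 10 of 13 and none fell (camera adjusted p = 1.12e-05, adjusted p = 0.133 with an estimated correlation). Exhaustion and effector transcription factors rose in 14 of 20, such as Nr4a1 (68.9 ± 4.16 against 16.0 ± 4.07 CPM, 2.06) and Nr4a3 (2.02), which T cell receptor signals induce, while Zeb2 (-0.85) was lower (camera adjusted p = 1.01e-05, adjusted p = 0.137 with an estimated correlation). Immediate early and TCR-induced genes rose in 13 of 21, Tnfrsf9 (4-1BB) from 47.8 ± 4.59 to 224 ± 12.7 CPM (camera adjusted p = 2.14e-05, adjusted p = 0.325 with an estimated correlation). Cytokines and chemokines rose in 8 of 13, with 3 lower, Ltb (-1.04) among them (camera adjusted p = 0.00361, adjusted p = 0.133 with an estimated correlation). Cytotoxic genes rose in 8 of 17 and fell in 3 (Serpinb9 0.79, Gzmm -1.06), with camera adjusted p = 0.0371 and adjusted p = 0.332 with an estimated correlation. Glycolysis genes rose in 10 of 16 (Tpi1 1.12), oxidative phosphorylation genes in 16 of 23 (9 under total-read scaling) and cholesterol synthesis genes in 10 of 19. These metabolic lists had camera adjusted p = 3.98e-05, 8.56e-06 and 0.00224, and adjusted p = 0.189, 0.189 and 0.332 with an estimated correlation.

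Quiescence genes fell in 14 of 20 (Pik3ip1 -1.54), trafficking receptors in 11 of 20 (S1pr5 -1.65, Itga1 -1.20), progenitor-like genes in 12 of 20 and interferon-stimulated genes in 12 of 25 (Ifit3 -1.23). In that order camera adjusted p = 1.13e-08, 1.01e-05, 2.84e-05 and 4.84e-05, and adjusted p = 0.137, 0.137, 0.137 and 0.350 with an estimated correlation. Of the progenitor-like list Xcl1 (1.43) and Myb (0.67) were among 3 that rose. CX3CR1 KLRG1 effector genes fell in 10 of 18 (Klf3 -1.12), with Itgam (0.59) among 3 that rose (camera adjusted p = 0.00582, adjusted p = 0.332 with an estimated correlation). NK receptors fell in 6 of 12 (Klra9 -1.43), with Cd244 (0.95) higher (camera adjusted p = 0.0137, adjusted p = 0.332 with an estimated correlation). Camera did not pass ribosomal proteins (1 higher and 1 lower of 24), tissue residency (5 and 4 of 14, Hic1 0.98) or apoptosis regulators (8 and 3 of 17, Bbc3 -1.19). Adjusted over the list alone, the counts differed in cytotoxic genes (9 higher), cytokines (9 higher and 4 lower), glycolysis (11 higher), oxidative phosphorylation (19 higher), apoptosis regulators (4 lower) and ribosomal proteins (0 and 0). They also differed by 1 gene each in markers of plasma cells, macrophages, dendritic cells and erythroid cells.

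Tim3+CX3CR1− and Tim3+CX3CR1+, both YFP+ and Tim3+, differ in the sort by CX3CR1 alone, and this contrast gave the fewest called genes. Tim3+CX3CR1− cells had lower effector and NK receptor transcripts and higher S phase, metabolic and ribosomal protein transcripts by camera, calls that all ended with an estimated correlation between genes. Beside Cx3cr1 (-4.05 ± 0.12 SE), the lowest changes were in S1pr5 (5.16 ± 1.54 against 27.0 ± 5.12 CPM) and Itgam (70.8 ± 3.45 against 278 ± 27.5, -1.95). Next were Lrrc75b (2.70 ± 0.435 against 10.7 ± 2.12, -1.66) and the chitinase gene Chit1 (12.9 ± 0.849 against 40.6 ± 2.43, -1.58), and limma adjusted p for these 5 ran from 2.84e-12 to 7.89e-06. In the panel, Tox (399 ± 42.5 against 622 ± 58.6 CPM, -0.64) and Tbx21 (157 ± 9.08 against 235 ± 14.5, -0.57) fell as well, with limma adjusted p = 0.000445 and 4.36e-05. Prdm1 (-0.03), Havcr2 (-0.14), Tcf7 (-0.06), Eomes (-0.13), Gzmb (-0.22), Klrg1 (-0.36), Mki67 (0.22), Cd101 (0.17) and Cxcr6 (-0.30) did not pass (limma adjusted p = 0.926, 0.473, 0.840, 0.332, 0.372, 0.140, 0.307, 0.348 and 0.0555). With a replicate block for mouse Klrg1 and Cxcr6 passed (limma adjusted p = 0.0307 and 0.0173), and Cxcr6 also without the Tim3+CX3CR1− library of mouse 45 (-0.36, limma adjusted p = 0.0470).

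The calls of 4 further panel genes ended when some single libraries were left out, with the direction of change kept. Pdcd1 stood at -0.27 (limma adjusted p = 0.0314, range over its alternatives 0.00339 to 0.304). Without the Tim3+CX3CR1− library of mouse 45, 49 or 54 it was at -0.29, -0.25 and -0.28, with limma adjusted p = 0.0626, 0.0989 and 0.0745. Leaving out the Tim3+CX3CR1+ library of mouse 49 or 54 put Pdcd1 at -0.25 and -0.27, with limma adjusted p = 0.1 and 0.0742. Cd8a stood at -0.26 (limma adjusted p = 0.0159, range 0.00538 to 0.209). Leaving out the Tim3+CX3CR1− library of mouse 45 or 54 or the Tim3+CX3CR1+ library of mouse 49 put Cd8a at -0.23, -0.25 and -0.25, with limma adjusted p = 0.0737, 0.0631 and 0.0519. Slamf6 stood at 0.28 (limma adjusted p = 0.0286, range 0.000564 to 0.146). Slamf6 without the Tim3+CX3CR1+ library of mouse 45 or 54 or the Tim3+CX3CR1− library of mouse 49 was at 0.25, 0.23 and 0.20, with limma adjusted p = 0.0958, 0.117 and 0.146. Id3, at 1.95 ± 0.0807 against 0.786 ± 0.207 CPM, stood at 0.73 (limma adjusted p = 0.0227, range 0.00386 to 0.238). When the Tim3+CX3CR1− library of mouse 45 or 54 or the Tim3+CX3CR1+ library of mouse 49 was left out, Id3 was at 0.71, 0.72 and 0.64, with limma adjusted p = 0.0609, 0.0611 and 0.0825.

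The 5 genes with the highest change for Tim3+CX3CR1− over Tim3+CX3CR1+ were Vsig8 (259 ± 237 against 17.8 ± 5.03 CPM, 3.05 ± 0.97 SE), Cadps2 (355 ± 406 against 22.3 ± 6.46, 3.01 ± 1.01) and Itsn1 (319 ± 305 against 22.9 ± 8.59, 3.01 ± 1.02), then Mroh6 (63.6 ± 59.6 against 4.21 ± 0.996, 2.98 ± 0.87) and Pnck (154 ± 131 against 12.5 ± 4.27, 2.90 ± 0.90). In this order limma gave adjusted p = 0.0314, 0.0404, 0.0418, 0.0203 and 0.0269. Their SD in Tim3+CX3CR1− was close to their mean: Vsig8 was at 501, 26.9 and 249 CPM in mice 45, 49 and 54. Gm42418, a transcript of the ribosomal RNA repeat, was at 22400, 1380 and 13200 CPM in the same libraries, at 11900 CPM in the YFP-negative library of mouse 49 and at 4280 CPM in the Tim3−CX3CR1+ library of mouse 49. The other 8 libraries, that of mouse 49 from Tim3+CX3CR1− included, had 867 to 1440 CPM. With log2 Gm42418 as a covariate the 5 changes were 0.07, -0.06, -0.11, 0.33 and 0.16. Without the Tim3+CX3CR1− library of mouse 45 or 54 or the Tim3+CX3CR1+ library of mouse 49, none of the 5 passed. Their changes were 1.94 to 2.19, 2.54 to 2.87 and 2.66 to 2.87, with limma adjusted p of 0.115 to 0.216, 0.0779 to 0.139 and 0.0597 to 0.115. Without the Tim3+CX3CR1+ library of mouse 45, Vsig8, Cadps2, Itsn1 and Pnck stood at 3.03, 3.09, 2.98 and 2.92 (limma adjusted p = 0.0713, 0.0762, 0.0893 and 0.0592). Without that of mouse 54 Vsig8, Cadps2 and Itsn1 stood at 3.25, 3.18 and 3.28 (limma adjusted p = 0.0537, 0.0699 and 0.0624). Over all alternatives the limma adjusted p of these 5 genes ran from 7.46e-08 to 0.932, and with a replicate block for mouse Itsn1 had limma adjusted p = 0.0521.

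CX3CR1 KLRG1 effector genes fell in 13 of 18 and none rose in Tim3+CX3CR1− over Tim3+CX3CR1+ (Zeb2 -1.34, camera adjusted p = 2.89e-14, adjusted p = 0.0948 with an estimated correlation). NK receptors fell in 9 of 12 (Klra3 -1.40, camera adjusted p = 4.28e-07, adjusted p = 0.0948 with an estimated correlation). S phase genes rose in 19 of 20 by a median of 0.48 (Ung 0.66, Rrm2 0.63), with camera adjusted p = 2.09e-14 and adjusted p = 0.0948 with an estimated correlation. G2 and M phase genes rose in 7 of 20 and none fell (camera adjusted p = 0.000220, adjusted p = 0.337 with an estimated correlation). Oxidative phosphorylation genes rose in 16 of 23 (Atp5b 1460 ± 46.3 against 969 ± 16.1 CPM, 0.59), ribosomal protein genes in 15 of 24 (Rps2 0.77), cholesterol synthesis genes in 10 of 19 (Fdps 0.78) and glycolysis genes in 9 of 16 (Tpi1 1.03, Ldha 0.68). In that order camera adjusted p = 2.30e-10, 5.59e-07, 3.88e-06 and 1.19e-05, and adjusted p = 0.0948, 0.0948, 0.225 and 0.217 with an estimated correlation. Progenitor-like genes rose in 8 of 20, Xcl1 (1.41) and Myb (0.94) the most, and Bach2 (-0.96) and Socs3 (-0.33) fell (camera adjusted p = 0.00367, adjusted p = 0.237 with an estimated correlation). Interferon-stimulated genes fell in 13 of 25, quiescence genes in 12 of 20 (Txnip -0.85), trafficking receptors in 9 of 20 with 2 higher, transcription factors in 7 of 20 with 1 higher, and cytotoxic genes in 4 of 17 (Ctsw -0.64). Camera gave them adjusted p = 5.50e-06, 1.98e-06, 0.00242, 0.000744 and 0.00503, and adjusted p = 0.337, 0.225, 0.237, 0.225 and 0.237 with an estimated correlation.

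Camera did not pass inhibitory receptors (0 higher and 5 lower of 13, Entpd1 -0.53), cytokines and chemokines (5 and 3 of 13, Il21 1.08, Ccl5 -1.21) or immediate early genes (1 and 3 of 21, Fosl2 -0.97) for Tim3+CX3CR1− over Tim3+CX3CR1+. It did not pass tissue residency (1 and 1 of 14, Bhlhe40 -0.46) or apoptosis regulators (0 and 4 of 17, Bcl2 -1.07) either. Macrophage and monocyte markers fell in 5 of 8, Lyz2 from 7.33 ± 2.06 to 2.14 ± 0.373 CPM (camera adjusted p = 0.00156, adjusted p = 0.0948 with an estimated correlation). Adjusted over the list alone, the counts were 10 higher for progenitor-like genes, 1 higher for inhibitory receptors, 9 lower for transcription factors, 1 higher for effector genes, 10 lower for NK receptors and 12 higher for G2 and M phase. They were 5 higher and 11 lower for trafficking, 15 lower for interferon-stimulated genes, and 2 higher and 13 lower for quiescence. They were 10 higher for glycolysis, 21 higher for oxidative phosphorylation, 11 higher for cholesterol synthesis and 7 lower for macrophage markers, and otherwise as above. The total of 3407 called genes was 1829 with log2 Gm42418 as a covariate and 1656 or 2243 without the 4 libraries of mouse 45 or 49, all alternatives chosen after seeing the data.

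The last comparison, Tim3+CX3CR1− over Tim3−CX3CR1+, spans YFP+ cells that differ in both Tim3 and CX3CR1. By camera, the cell cycle, metabolic, and cytokine and chemokine lists were higher in Tim3+CX3CR1− cells and the effector, NK receptor and quiescence lists lower. With an estimated correlation between genes, each of these list calls ended. The highest changes were in the cytokine Il21 (19.2 ± 3.63 against 1.00 ± 0.473 CPM, 3.34 ± 0.21 SE) and the amino acid transporter gene Slc16a10 (25.7 ± 1.56 against 2.58 ± 0.134, 2.90). Next were Xcl1 (20.9 ± 3.26 against 2.10 ± 0.616, 2.83), Serpine2 (24.8 ± 3.56 against 2.77 ± 0.702, 2.78) and Aunip (20.4 ± 1.16 against 2.28 ± 0.717, 2.72). The lowest were in Cx3cr1 (-4.59), S1pr5 (-3.85), Klrb1c (1.75 ± 0.308 against 30.5 ± 12.3, -3.46), Tnfrsf25 (-3.14) and Tcf7 (-2.98). All 10 passed limma with adjusted p from 3.75e-13 to 1.05e-07. In the panel, Prdm1 (0.61), Havcr2 (2.08), Pdcd1 (0.86), Eomes (0.33), Gzmb (0.85) and Mki67 (1.65) rose, and Cd8a (-0.27), Tbx21 (-0.77) and Cxcr6 (-0.48) fell with Cx3cr1 and Tcf7. Slamf6 (0.12), Tox (-0.03), Klrg1 (-0.37) and Cd101 (0.23) did not pass (limma adjusted p = 0.267, 0.828, 0.0743 and 0.120). Id3 stood at -0.63 (limma adjusted p = 0.0236, range over its alternatives 0.00145 to 0.259). Without the Tim3+CX3CR1− library of mouse 49 or 54 or the Tim3−CX3CR1+ library of mouse 49 Id3 was at -0.61, -0.64 and -0.31, with limma adjusted p = 0.0591, 0.0507 and 0.145. Klrg1 passed without the Tim3+CX3CR1− library of mouse 49 (-0.49, limma adjusted p = 0.0409) and with a replicate block for mouse (limma adjusted p = 0.0132, range over its alternatives 0.0114 to 0.292). Cd101 passed without the Tim3−CX3CR1+ library of mouse 49 (0.32, limma adjusted p = 0.0491) or the Tim3+CX3CR1− library of mouse 54 (0.34, limma adjusted p = 0.0414, range 0.0121 to 0.497). Cd8a did not pass without the 4 libraries of mouse 45 or of mouse 54 (limma adjusted p = 0.122 and 0.0751).

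All 20 G2 and M phase genes and all 20 S phase genes rose in Tim3+CX3CR1− over Tim3−CX3CR1+, by medians of 1.76 and 1.75, with Bub1 at 2.14 and Rrm1 at 2.10. Camera adjusted p = 2.66e-18 and 6.33e-19, and adjusted p = 0.142 with an estimated correlation for each. All 23 oxidative phosphorylation genes rose by a median of 0.56 (Atp5b 1.08, Cyc1 0.92). Of the other metabolic lists, 13 of 16 glycolysis genes rose (Tpi1 263 ± 15.6 against 58.6 ± 2.09 CPM, 2.15, and Ldha 1.47) with Slc2a1 (-0.41) lower, and 16 of 19 cholesterol synthesis genes rose (Cyp51 1.41). For these 3 lists camera adjusted p = 9.30e-10, 4.87e-06 and 7.12e-06, and adjusted p = 0.142, 0.149 and 0.216 with an estimated correlation. Ribosomal protein genes rose in 14 of 24 (9 under total-read scaling, with 1 lower), inhibitory receptors in 7 of 13 (Cd200r1 1.36) and transcription factors in 11 of 20 with 3 lower (Nr4a1 2.17, Zeb2 -2.19). Immediate early genes rose in 9 of 21 with 4 lower (Egr2 2.46, Ier5 -0.64) and cytokines and chemokines in 9 of 13 with 3 lower (Ccl5 -1.66). From ribosomal proteins to cytokines, camera adjusted p = 0.00765, 0.00733, 0.0353, 0.0139 and 0.0111, and adjusted p = 0.323, 0.248, 0.395, 0.477 and 0.142 with an estimated correlation. CX3CR1 KLRG1 effector genes fell in 14 of 18, NK receptors in 9 of 12 (Klra9 -2.36) and quiescence genes in 17 of 20 (Klf3 -2.05). Also lower were trafficking receptors in 12 of 20, interferon-stimulated genes in 22 of 25 (Ifit3 -1.98, Rsad2 -1.19) and progenitor-like genes in 11 of 20 with 3 higher (Myb 1.61). From effector to progenitor-like genes, camera adjusted p = 7.93e-08, 6.07e-05, 2.71e-08, 3.01e-05, 3.98e-07 and 0.0449, and adjusted p = 0.142, 0.149, 0.149, 0.149, 0.351 and 0.395 with an estimated correlation. Camera did not pass cytotoxic genes (7 higher and 5 lower of 17, Ctsw -0.89), tissue residency (5 and 6 of 14) or apoptosis regulators (6 and 5 of 17, Bcl2 -1.70). Adjusted over the list alone, the counts differed in transcription factors (4 lower), cytotoxic genes (8 higher), effector genes (15 lower), trafficking (14 lower), glycolysis (14 higher) and markers of macrophages, neutrophils and dendritic cells (0 and 0).

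**Figure D3:**
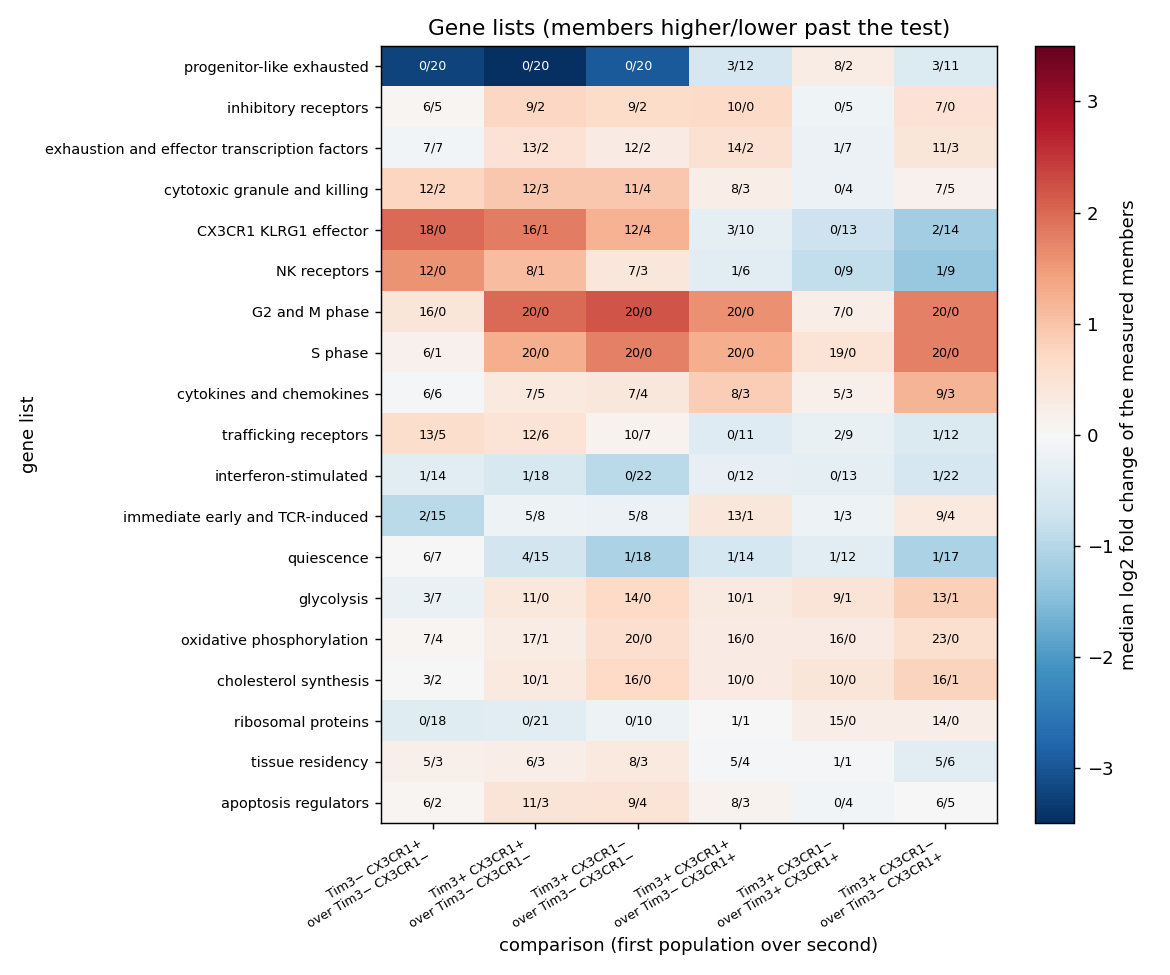
Gene lists (vertical axis) in the 6 comparisons (horizontal axis), with the median log2 change of the measured members as colour and the members higher and lower past an adjusted p of 0.05 as text. The progenitor-like list has 20 members lower in each comparison with the YFP-negative population, and the G2 and M phase list has 20 higher in all comparisons but Tim3−CX3CR1+ over YFP-negative and Tim3+CX3CR1− over Tim3+CX3CR1+.

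Counting genes higher in a population than in each of the other 3, 1707 were highest in the YFP-negative population, 537 in Tim3−CX3CR1+, 1104 in Tim3+CX3CR1− and 155 in Tim3+CX3CR1+. In 20 simulations with no effect in any gene this count was 0 in each population. With an adjusted p asked of 3 comparisons at once, 0 is near certain there, so the simulations give no level to compare with. Independent lists of the same sizes would share 174, 100, 118 and 101 genes. The 3 comparisons behind each count share the libraries of that population, too few to be split, so part of the excess may come from them. Highest in the YFP-negative population by the widest margins were Nsg2, Ccr7, Id3, the chemokine receptor Ccr6 (42.5 ± 3.07 CPM, at most 0.815 elsewhere), Lrig1, Tnfsf8 (178 ± 19.8, at most 6.67), P2rx7 and Aff3. In Tim3−CX3CR1+ they were Klrb1c, Cpne7, the inhibitory Fc receptor gene Fcgr2b (20.3 ± 2.43, at most 5.55), S1pr5, the retinoic acid receptor gene Rara (65.4 ± 5.67, at most 25.9), Lrrc75b, Nhsl2 and the integrin Itga1. In Tim3+CX3CR1− they were Nos1 (12.9 ± 1.98, at most 4.51), Cacna1i, Nt5dc2, the cyclin gene Ccne2 (54.6 ± 21.5, at most 23.8), Aunip, Tpi1 and the histone gene Hist1h1c (21.6 ± 8.12, at most 9.56). Among these genes the SD was largest relative to the mean for Ccne2 and Hist1h1c. In Tim3+CX3CR1+ they were Prr5l (123 ± 4.90, at most 58.1), H2-Aa, which is also on the dendritic cell marker list, Gem (141 ± 8.68, at most 86.9), C1qtnf6, Chn2, Pabpc1l, Itgam and Fgr. The 155 of Tim3+CX3CR1+ varied with the libraries used, being 66 without the Tim3+CX3CR1+ library of mouse 49 and 95 without the Tim3+CX3CR1− library of mouse 54. Among alternatives chosen after seeing the data, the 1707 of the YFP-negative population became 1056 without the 4 libraries of mouse 54, and the 1104 of Tim3+CX3CR1− became 701 with log2 Gm42418 as a covariate and 582 without mouse 45. The 537 of Tim3−CX3CR1+ became 889 with array weights and 240, 340 and 334 without mouse 45, 49 and 54. The 155 of Tim3+CX3CR1+ became 87 under total-read scaling, 65 with log2 Gm42418 as a covariate, and 33 and 51 without the 4 libraries of mouse 45 and of mouse 49.

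Markers of other cell types were summed per library. Summed B cell markers (5 measured) were at 411 ± 53.0 CPM in the YFP-negative population and at 125 ± 6.87, 132 ± 8.40 and 158 ± 5.03 CPM in Tim3−CX3CR1+, Tim3+CX3CR1+ and Tim3+CX3CR1−. Ighm gave 317 and Cd22 77.2 CPM of the first sum, and Cd79a and Cd79b gave 1.83 and 8.29 CPM. Each YFP+ population differed from it with an exact permutation p = 0.1, the smallest that 3 libraries against 3 can give. CD4 T cell markers (5) were at 150 ± 19.2, 134 ± 11.9, 128 ± 3.15 and 123 ± 2.54 CPM, of which Ctla4, which CD8 T cells also express, gave 109, 77.2, 77.7 and 73.0. Cd4 was at 3.06 CPM or lower and Foxp3 reached 3.95 CPM in Tim3+CX3CR1−. Macrophage and monocyte markers (8) were at 56.0 ± 3.49, 53.5 ± 2.01, 67.6 ± 4.64 and 42.3 ± 4.93 CPM, and dendritic cell markers (7) at 43.4 ± 10.8, 53.9 ± 7.21, 66.1 ± 9.80 and 42.9 ± 2.74. Plasma cell markers (6) were at 41.9 ± 8.19, 58.9 ± 3.77, 48.5 ± 12.6 and 33.1 ± 4.70, and neutrophil markers (5) at 4.26 ± 1.07, 8.61 ± 2.73, 4.96 ± 2.12 and 4.22 ± 0.658. Erythroid and platelet markers (2, too few for a list test) were at 1.63 ± 1.17, 2.85 ± 1.45, 1.37 ± 0.756 and 1.70 ± 1.46. The exact permutation p of 0.1 was not particular to B cell markers. Summed markers of plasma cells, neutrophils, dendritic cells and CD4 T cells also reached it in some comparisons. Macrophage and monocyte markers reached it in all but Tim3−CX3CR1+ over YFP-negative. Of these 8 markers, 6 were called higher and 1 lower in Tim3+CX3CR1+ over YFP-negative (median 0.80, camera adjusted p = 0.0727). Besides the B cell list against the YFP-negative population and the macrophage list for Tim3+CX3CR1− over Tim3+CX3CR1+, camera passed none of these lists. Some lists that did not pass had a median and a mean or test of opposite sign, such as CD4 T cell markers for Tim3+CX3CR1− over Tim3+CX3CR1+ (median -0.07, mean 0.48) and B cell markers for Tim3+CX3CR1− over Tim3−CX3CR1+ (median -0.21, mean 0.01).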

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

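Array weights, scaling by total reads, median-of-ratios scaling, the deposited log2 values, the 2 covariates and the fits without a mouse were chosen only after the results were seen. Counts of called genes stayed within 1.5 times their value for all 6 comparisons with no filter, pseudocounts of 0.25 and 5, limma-voom, the 6 libraries of a comparison alone, the block, array weights, the 3 other scales and the satellite covariate. No gene called in both fits changed direction in any of these. A DESeq2 Wald test and edgeR with DESeq2 size factors in place of TMM, both written down beforehand, were not run, and limma-voom was the model of the recovered reads that was. Without the 4 libraries of mouse 45 or of mouse 49, Tim3+CX3CR1+ over Tim3−CX3CR1+ had 3104 and 3434 genes in place of 5199, and Tim3+CX3CR1− over Tim3+CX3CR1+ had 1656 and 2243 in place of 3407, fits with fewer libraries. With log2 Gm42418 as a covariate the latter had 1829 and genes highest in Tim3+CX3CR1− numbered 701 in place of 1104, a fit that also removes part of the population difference. Without mouse 45 that count was 582. Genes highest in the YFP-negative population numbered 1056 without mouse 54 in place of 1707. Those highest in Tim3−CX3CR1+ (537) numbered 889 with array weights, for which the cause was not tested, and 240, 340 and 334 without mouse 45, 49 and 54. Those highest in Tim3+CX3CR1+ (155) numbered 87 with total-read scaling, 65 with the Gm42418 covariate, and 33 and 51 without mouse 45 and mouse 49. The cause of the first was not tested.

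Leaving out 1 library at a time gave 4815 to 5809, 6256 to 6449 and 6972 to 7166 genes for Tim3−CX3CR1+, Tim3+CX3CR1+ and Tim3+CX3CR1− over YFP-negative. It gave 3943 to 5524 for Tim3+CX3CR1+ over Tim3−CX3CR1+, 2360 to 2913 for Tim3+CX3CR1− over Tim3+CX3CR1+ and 6445 to 7438 for Tim3+CX3CR1− over Tim3−CX3CR1+. Highest genes ran from 1278 to 1708 in the YFP-negative population, 363 to 795 in Tim3−CX3CR1+ and 781 to 1151 in Tim3+CX3CR1−. In Tim3+CX3CR1+ they ran from 66 (without its library of mouse 49) to 177 (without the YFP-negative library of mouse 54), and were 95 without the Tim3+CX3CR1− library of mouse 54.

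With the mouse as a block, Tim3−CX3CR1+, Tim3+CX3CR1+ and Tim3+CX3CR1− over YFP-negative had 5947, 6972 and 7639 genes. Tim3+CX3CR1+ over Tim3−CX3CR1+ had 5321, Tim3+CX3CR1− over Tim3+CX3CR1+ 3496 and Tim3+CX3CR1− over Tim3−CX3CR1+ 7445. Highest genes under the block numbered 1722, 576, 1130 and 162 in YFP-negative, Tim3−CX3CR1+, Tim3+CX3CR1− and Tim3+CX3CR1+. Under the block Itsn1 and 4 other named genes no longer passed: by limma, Zbtb46 for Tim3+CX3CR1− over YFP-negative had adjusted p = 0.0576 (0.00717 to 0.524 over its alternatives) and Rps2 for Tim3+CX3CR1+ over Tim3−CX3CR1+ had 0.0510 (0.000508 to 0.281). For Tim3+CX3CR1− over Tim3−CX3CR1+, limma gave C1qa an adjusted p of 0.0519 (0.00283 to 0.322) and Ly6g one of 0.0531 (0.0392 to 0.134). Klrg1 and Cxcr6 for Tim3+CX3CR1− over Tim3+CX3CR1+ and Klrg1 for Tim3+CX3CR1− over Tim3−CX3CR1+ newly passed under the block, with the values given in the report. The block changed no other call of a named gene and no list call (86 of 150).

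With the correlation between genes estimated per list, 4 of 86 list calls passed: the progenitor-like list lower in each comparison with YFP-negative, and the CX3CR1 KLRG1 effector list higher in Tim3−CX3CR1+ over YFP-negative. Fry, which asks another question, called 120. Among 533 results of named genes, 11160 pairs with an alternative gave 10677 calls on the same side of the threshold in the same direction, 451 that no longer passed, 30 that newly passed and 2 that changed sign. The latter were Cadps2 at -0.055 and Itsn1 at -0.106 for Tim3+CX3CR1− over Tim3+CX3CR1+ with the Gm42418 covariate, with limma adjusted p = 0.932 (from 1.36e-05 over its alternatives) and 0.794 (from 7.15e-07). Of 3184 pairs with 1 library of the 2 populations compared left out, 191 no longer passed and 0 changed sign. In reads simulated at these depths part even of the 4-fold changes was missed, and recovery was not split by gene level or depth.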

Other observations

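The tests of Gm42418 ratios, of the third component against satellite loci, depth and Gm42418, and of V segments within mice were chosen only after their results were seen, as were the genes given as lowest in a population.

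For each comparison the 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05, and 4 of these part all 3 mice. Of the 10 splits 1, the real one, gave as many genes in each comparison. Every other split mixes the populations on each side, so a difference between them adds to the spread within sides. Low counts there were near certain wherever the populations differ, and they give no level to compare the real count with. The real and the highest other counts were 5895 and 0 for Tim3−CX3CR1+ over YFP-negative, 6925 and 0 for Tim3+CX3CR1+ over YFP-negative, and 7609 and 19 for Tim3+CX3CR1− over YFP-negative. They were 5199 and 0 for Tim3+CX3CR1+ over Tim3−CX3CR1+, 3407 and 1 for Tim3+CX3CR1− over Tim3+CX3CR1+, and 7398 and 0 for Tim3+CX3CR1− over Tim3−CX3CR1+.

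The 5 highest risers in Tim3+CX3CR1− over Tim3+CX3CR1+ (Vsig8, Cadps2, Itsn1, Mroh6 and Pnck) varied together with Gm42418, which overlaps ribosomal RNA, at r = 0.990 to 0.995 over 12 libraries. The median SD of their log2 ratio to Gm42418 was 0.270, against 1.90 for their own log2 level. Gm42418 stood at 22400 and 13200 CPM in the Tim3+CX3CR1− libraries of mice 45 and 54, at 11900 and 4280 CPM in the YFP-negative and Tim3−CX3CR1+ libraries of mouse 49, and at 867 to 1440 CPM in the other 8. Of the difference of 3.09 between the 2 Tim3+ populations, 0.30 ± 0.16 SE remained as a ratio to Gm42418, with the bound for this test also set after the values were seen, which argues against a difference of that size in these genes beyond Gm42418. Carryover of ribosomal and other non-polyadenylated RNA into some libraries is a candidate explanation for these 5 genes, and why it differs between libraries was not tested.

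The third principal component (10.6% of the variance) parted Tim3+CX3CR1− (-23.5, -6.8 and -16.3 in mice 45, 49 and 54) from Tim3+CX3CR1+ (2.1, 31.3 and 11.9), with Cx3cr1, S1pr5, Itgam and Zeb2 among the highest loadings, and it also spread the libraries within populations, where it followed summed satellite loci, taken here as a mark of genomic DNA, at r = -0.927 (permutation p = 0.00154, 0.00617 after adjustment over 4 relations; rho = -0.902; -0.916 without the 2 libraries farthest out). Summed CPM per kb of the 1439 lowest genes rose with the satellite loci at r = 0.892 (permutation p = 0.00540, 0.0108 adjusted, rho = 0.874, 0.831 without the 2), a test chosen before its result was seen. These CPM hold the 0.5 added to each read count, which weighs more in libraries of low depth. The satellite loci were left out of these lowest genes but not out of the component. The component also followed depth at r = 0.849 (p = 0.0131, 0.0175 adjusted; rho = 0.741; 0.821 without the 2), so genomic DNA reads and depth both stay open and may act together. With Gm42418 it gave r = -0.538 (p = 0.0625), and Cadps2, Itsn1, Pnck, Vsig8, Mroh6, Gm42418, Rpph1 and Lars2 are among the genes with the lowest loadings, so carryover of ribosomal and other non-polyadenylated RNA stays open as well. Across 14396 genes the loadings had rho = 0.00572 with GC content and 0.116 with exonic length. The first value argues against GC bias as the source of the component as a whole. The loadings also hold the difference between populations, so they cannot tell whether GC bias adds to the spread within populations. The difference between the Tim3+ populations along the component stays open as untested, since the other tests address the spread within populations alone.

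Across 64 T cell receptor V segments, libraries of the same mouse deviated together from their population means, with a mean r of 0.571 and 18 of 18 pairs above 0 (permutation p = 0.00463 over 1296 relabellings, the smallest they can give), while centring pushes different mice below 0 (-0.285). Trav6-4 stood at 8.13, 6.59, 2.27 and 1.62 CPM in the Tim3+CX3CR1−, Tim3+CX3CR1+, Tim3−CX3CR1+ and YFP-negative libraries of mouse 49. It was at 0.950 CPM or lower in the other 2 mice. In the same order Trav5-1 stood at 7.54, 14.7, 7.33 and 2.40 CPM in mouse 54. In mice 45 and 49 it was at 1.22 CPM or lower in the YFP+ libraries. Their YFP-negative libraries had 0.864 and 2.51 CPM, so for Trav5-1 mouse 54 stood out in the YFP+ populations alone. Carryover from the YFP-negative library of the mouse would need a share as large as the slope of the deviations, whose smallest value less 2 SE was 42.6% (Tim3−CX3CR1+), where Tcf7 allows at most 9.45%. These SE count segments as replicates, though segments of a mouse are not independent, so they may be too small. For Tim3+CX3CR1+ and Tim3+CX3CR1− the slopes were 141 ± 12.8% and 143 ± 10.7% SE, against at most 1.45% and 1.25%, and carryover among YFP+ libraries was not tested. A repertoire shared by the 4 populations of a mouse may explain this pattern.

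Counting genes lower in a population than in each of the other 3, 1588 were lowest in the YFP-negative population, 873 in Tim3−CX3CR1+, 940 in Tim3+CX3CR1− and 47 in Tim3+CX3CR1+. Independent lists of the same sizes would share 199, 179, 112 and 52 genes, so the 47 of Tim3+CX3CR1+ are no excess. Simulations with no effect in any gene gave 0 in each, which was near certain and gives no level to compare with. The 3 comparisons behind a count share the libraries of that population. Genes lowest in Tim3−CX3CR1+ included members of the immediate early and TCR-induced list, of which 4 are given as examples. Egr2 of that list was lowest there too, while Fosl2 and Ier2 were higher there than in YFP-negative. Egr1 stood at 97.2 ± 22.8, 26.0 ± 1.75, 96.8 ± 9.91 and 82.8 ± 11.8 CPM in YFP-negative, Tim3−CX3CR1+, Tim3+CX3CR1+ and Tim3+CX3CR1− (n = 3). In the same order Nr4a1 stood at 51.9 ± 15.8, 16.0 ± 4.07, 68.9 ± 4.16 and 74.4 ± 9.75 CPM, Nr4a2 at 145 ± 28.8, 55.1 ± 8.35, 219 ± 8.45 and 194 ± 11.3, and Nr4a3 at 27.2 ± 8.39, 4.27 ± 0.534, 20.4 ± 2.33 and 21.6 ± 2.67. Lowest in Tim3+CX3CR1− were Bcl2, an inhibitor of cell death, at 299 ± 37.5, 307 ± 67.8, 197 ± 24.8 and 93.1 ± 13.7 CPM, and Bach2 at 52.5 ± 7.68, 25.7 ± 1.97, 15.2 ± 1.34 and 7.36 ± 1.15. Lowest in Tim3+CX3CR1+ was Gpr183 at 77.2 ± 5.68, 17.8 ± 1.34, 7.91 ± 1.09 and 16.9 ± 0.291 CPM. Sytl2 was lowest in YFP-negative at 9.60 ± 3.45 CPM, against 213 ± 18.4, 288 ± 15.3 and 152 ± 6.59.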
